A study of Gossypium hirsutum with 9 samples.

How the data were processed

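Transcript levels were measured by RNA sequencing. Total RNA came from fibres of field-grown upland cotton (Gossypium hirsutum) at 9 days post anthesis, from wild-type plants (WT) and from plants carrying an RNA interference construct against the transcription factor gene GhWRKY16 (RNAi). The labels list 9 samples, 3 WT and 6 RNAi. The values of 8 were used here, 3 WT and 5 RNAi libraries, and RNAi replicate 1 was not analysed here. Columns were matched to samples by their group letters and replicate number. Nothing says whether the replicates came from separate plants, so p-values measure the spread between these samples, which may be partly technical.

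The deposited values are FPKM per gene, 1 column per library, computed by the authors. FastQC, HISAT2 and DESeq 1.10.1 are named in the submitters' processing notes, without their role. The genome build, annotation and read counter are not given in the sources used here, and neither is the treatment of reads that fit several gene copies. Cotton carries near-identical A and D subgenome copies of most genes, so values of such pairs are uncertain where reads were split between them. The column sums ranged from 1200830 to 1296910 FPKM, and no pair of libraries was identical. Relative depth was estimated from low values: where whole reads were counted, the ratio of a gene's FPKM between 2 libraries is a ratio of small whole numbers times 1 constant per library pair. With a tolerance of 0.01 on the log2 scale and values under 0.5 FPKM, between 49.5% and 70.3% of the pairs of low values lay at ratios of up to 4 reads, against 1.7% to 3.3% at shifted constants. Relative to WT replicate 1, the depth was 1.76 in WT replicate 2 and 1.38 in WT replicate 3, and in RNAi replicates 2 to 6 it was 1.25, 1.83, 0.365, 2.19 and 1.11. The absolute number of reads is unknown, so no counting interval is given.

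Gene identifiers and symbols were used as the file pairs them. Of 70478 genes, 52552 had a symbol, which is the name of a similar gene in some organism and is shared by several cotton genes. None of the identifiers matched the reference table (assembly Gossypium_hirsutum_v2.1; 0 matches), so no gene coordinates are given. Chromosomes are those written in the identifiers.

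Genes with at least 1 FPKM in at least 3 libraries were tested (34051 genes, 27079 with a symbol) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes on this scale understate the change of low genes. The fit was tested on simulated values for the same 34051 genes in 3 and 5 libraries. It recovered 50 of 100 genes changed by 1 on the log2 scale and 93 of 100 changed by 2, with 7 false calls among 150. The simulated values were normal, independent between genes, and had the same SD in all libraries for a gene. Correlated genes and a library as shallow as RNAi replicate 4 were not simulated, so these rates may not hold for the real libraries. Gene lists (35) were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. The themes of the lists were fixed before the data were examined. Their members had been planned as description patterns, which could not be used because the file pairs identifiers only with symbols, and were rewritten as symbol patterns before any test but after the symbols were seen. For the mean of each list an exact permutation test over the 56 ways to choose 3 of 8 libraries was added after seeing the data. Its smallest p is 0.0179, so after adjustment over 35 lists a list could pass only if many lists reached that p. The design had been written for all 9 samples, and the 8 analysed were fitted the same way.

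The genes named were set by a rule fixed before the data were examined, except for its condition on names. They were the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold. Also required were groups that did not overlap, a mean of at least 5 FPKM in the higher group and a descriptive symbol. The rule had asked for a named description. The file pairs identifiers only with symbols, so a symbol other than a locus name took its place. From each described list, up to 3 members with the smallest adjusted p were added. Alternatives were other scalings of the libraries, pseudocounts of 0.1 and 0.01, other filters, a replicate block, subsets of the RNAi libraries, each library left out, array weights, no trend and other set tests.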

Results

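To ask how silencing of the WRKY transcription factor gene GhWRKY16 altered the transcriptome of elongating cotton fibres, the single-celled hairs of the seed coat, expression was compared between 3 WT and 5 RNAi libraries at 9 days post anthesis. Expression was given as FPKM, without read counts. The relative depth derived from low values was lowest in RNAi replicate 4, at 0.365 of WT replicate 1, and highest in RNAi replicate 5, at 2.19. Pairwise correlations of log2(FPKM + 1) across 34051 genes, which are not independent replicates, ranged from 0.930 to 0.982. The median was 0.970 within WT, 0.962 within RNAi and 0.964 between the groups. RNAi replicate 4 had the lowest mean correlation with the others, 0.940, and carried 32.9% of its FPKM in genes without a symbol, against 27.2% to 29.7% in the other 7 libraries.

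The silenced gene itself was not identified by name among the genes of the file. The reduction of GhWRKY16 was therefore not measured here, and the labels could not be checked against it. Of the 8 genes with a WRKY symbol on A01 and D01, the chromosomes of the 2 genes that the reference table (assembly Gossypium_hirsutum_v2.1) also calls WRKY16, 4 were listed at 0 in every library. Among the 3 that could be tested, the limma adjusted p ranged from 0.877 to 0.978, and whether any of the 8 is the target is not known. The WRKY family, the plant transcription factors that bind W-box promoter elements, was examined in its place. None of its 62 tested members passed limma's threshold, adjusted over all genes or over the list alone, and 7 had an unadjusted p under 0.05. Their log2 fold change (RNAi minus WT) was negative in 42 members. As a list the WRKY genes lay at the edge of the threshold, with an adjusted p of 0.0517 by camera and an adjusted p of 0.873 with an estimated correlation. The lowest p among them belonged to Gh_D06G0175 (WRKY7), at 4.60 ± 1.46 FPKM in WT (SD, n = 3) and 1.81 ± 0.512 in RNAi (SD, n = 5). Its log2 fold change was -0.99 ± 0.21 (SE), with a limma adjusted p of 0.215. Its namesake Gh_A06G0179 (WRKY7) stood at 4.40 ± 3.39 and 1.02 ± 0.325 FPKM (limma adjusted p = 0.451). Gh_A11G0997 (WRKY65) stood at 1.94 ± 0.616 and 0.920 ± 0.346 FPKM (limma adjusted p = 0.733). Over 20 alternatives the list passed camera in 10, with adjusted p values from 9.8e-04 without RNAi replicate 2 to 0.662 with RNAi replicates 2 and 3 only. It also passed when rescaled (0.0357 by median ratio) or without WT replicate 3 (0.0475) or RNAi replicate 6 (0.0489), and it did not pass with no filter (0.620) or a filter at 5 FPKM (0.498).

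Few genes passed the threshold between RNAi and WT, some of them with a large change. In simulated values the fit recovered 50 of 100 genes changed by 1 on the log2 scale, so more genes may have changed. Of 34051 genes, 27 rose and 30 fell, and 53 of these 57 changed at least 2-fold on the log2(FPKM + 1) scale (24 rose, 29 fell). The largest rise was in Gh_A01G0110 (TFT6, named after a tomato member of a family of phosphoprotein-binding regulators), from 2.07 ± 0.434 FPKM in WT to 158 ± 6.87 in RNAi. Its log2 fold change was 5.70 ± 0.12 (SE; limma adjusted p = 1.9e-08). Gh_D05G3507, without a symbol and so outside the naming rule, rose from 4.67 ± 0.994 to 56.6 ± 30.5 FPKM. It is given after its values were seen. Gh_D09G1418 (UBQ11, a polyubiquitin) rose from 5.42 ± 1.31 to 55.5 ± 16.1 FPKM, and Gh_D02G0431 (PRP) from 4.91 ± 1.28 to 37.8 ± 10.5 FPKM. Gh_D06G0237 (KLHL30) averaged 79.5 ± 4.78 FPKM in RNAi, while WT replicate 1 had 9.45 and the other WT libraries were listed at 0 (limma adjusted p = 0.0156). Among enzymes, Gh_D12G1712 (DBR, a double-bond reductase) rose from 3.0 ± 0.525 to 14.6 ± 4.73 FPKM. Gh_A11G1434 (CPX1, coproporphyrinogen oxidase of tetrapyrrole synthesis) rose from 10.3 ± 0.702 to 30.9 ± 3.72 FPKM and Gh_A08G1909 (GME-1, GDP-mannose epimerase of ascorbate synthesis) from 5.04 ± 0.594 to 12.1 ± 1.26. Gh_D11G2510 (TUBB2, a beta-tubulin of microtubules) rose from 8.70 ± 0.494 to 21.6 ± 2.38 FPKM. Gh_D09G1844 (SAP7, a zinc finger stress-associated protein) rose from 35.3 ± 1.48 to 71.2 ± 5.55 FPKM and Gh_D10G2504 (TOPP4, a protein phosphatase) from 7.68 ± 0.303 to 13.8 ± 1.01.

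Among the genes that fell, several were nearly silent in RNAi. The largest falls were in genes without a symbol, which the naming rule leaves out and which are given after their values were seen. Gh_A11G1809 fell from 21.1 ± 6.43 FPKM in WT to 0.221 ± 0.403 in RNAi, and Gh_A04G0376 from 17.7 ± 4.03 to 0.0968 ± 0.133. Gh_A05G3470 (NQR, a quinone reductase) fell from 12.1 ± 1.49 FPKM in WT to 0.358 ± 0.229 in RNAi. Its log2 fold change was -3.28 ± 0.18 (SE; limma adjusted p = 1.0e-04). Gh_A01G0095 (MRS2-3, a magnesium transporter) fell from 22.7 ± 1.24 to 1.57 ± 0.957 FPKM (limma adjusted p = 8.3e-04). RNAi replicate 4 had 3.22 FPKM of it and the other RNAi libraries 0.954 to 1.59. Gh_D11G0596 (DGAT2, which makes storage lipid) fell from 7.98 ± 2.64 to 0.50 ± 0.304 FPKM, and Gh_A08G2009 (LCAT3, a phospholipase) from 11.1 ± 4.12 to 1.82 ± 0.411, with RNAi replicate 2 lowest at 1.11. Gh_A03G2066 (ISY1, a pre-mRNA splicing factor) fell from 7.43 ± 1.59 to 1.31 ± 0.211 FPKM, and Gh_A11G1349 (ycf4, named after a plastid gene for photosystem assembly) from 5.59 ± 3.10 to 0.284 ± 0.222. Gh_D13G0139 (WUN1, a wound-induced protein) fell from 45.4 ± 29.1 to 3.33 ± 0.943 FPKM, although the WT libraries themselves ranged from 15.1 to 73.1. Among the more abundant genes, Gh_A08G0107 (DIR19, a dirigent protein) fell from 128 ± 28.7 to 47.1 ± 11.2 FPKM and Gh_A08G0104 (YLS3) from 31.3 ± 0.811 to 12.6 ± 2.36. Gh_A12G1273 (ENT1, a nucleoside transporter) fell from 8.45 ± 0.656 to 3.30 ± 0.650 FPKM, and its D-subgenome namesake Gh_D12G1439 (ENT1), named after its values were seen, fell from 60.6 to 30.9 FPKM.

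**Figure D1:**
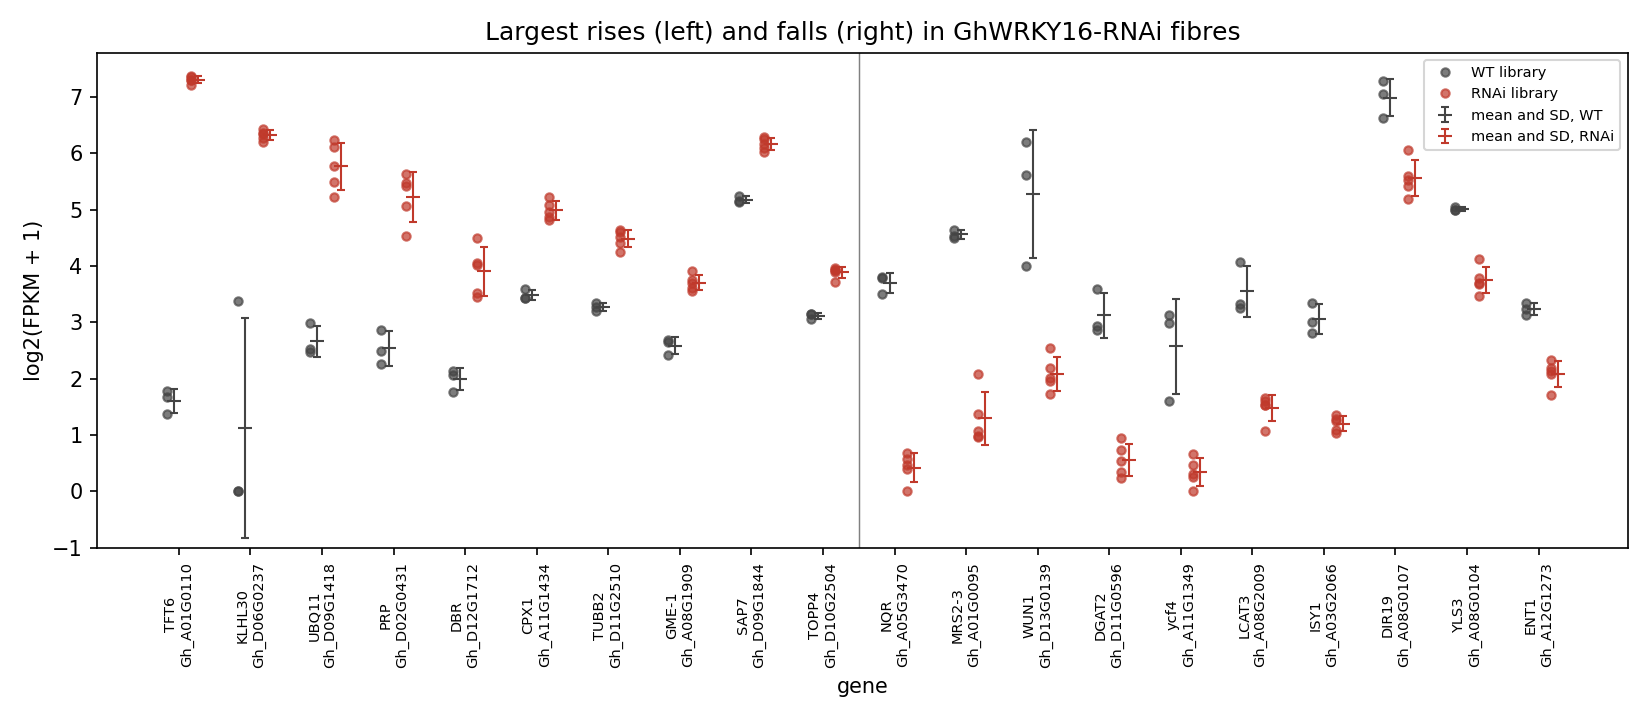
Expression as log2(FPKM + 1) of the named genes, with a point per library and the mean ± SD of the 3 WT and 5 RNAi libraries. These had the 10 largest rises and 10 largest falls under the naming rule. The rule asks for a descriptive symbol and a mean of at least 5 FPKM in the higher group, so some larger changes are not shown. The values of both groups are separate for each gene, and TFT6 lies near 2.07 FPKM in WT and 158 FPKM in RNAi.

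The groups did not overlap in 1386 of all 34051 tested genes (4.07%), against the 3.57% that chance gives. The 57 genes were among these, as their selection by the same difference makes likely. At an unadjusted p under 0.05 there were 1996 genes, against 1703 that chance alone would give among 34051. With single libraries left out, this number ranged from 1064 (without WT replicate 3) to 2564 (without WT replicate 2). The excess over chance therefore depends on which libraries are used. The count of 57 fell to 33 without WT replicate 2 or WT replicate 3, to 34 without RNAi replicate 5 and to 37 without RNAi replicate 2. Of the 20 genes, 11 stayed past the threshold when any single library was left out. The other 9 lost it without at least 1 library. The highest adjusted p was reached without WT replicate 1 for GME-1 (0.050) and without WT replicate 2 for DBR (0.108), TOPP4 (0.190), WUN1 (0.135), ycf4 (0.225) and YLS3 (0.0638). It was reached without WT replicate 3 for KLHL30 (0.103), DIR19 (0.211) and ENT1 (0.191).

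Of the 5 lists of wall growth, cellulose synthases, arabinogalactan proteins and expansins stood higher in the RNAi libraries by camera at the preset correlation, and those of xyloglucan and pectin enzymes did not pass. With an estimated correlation all 3 calls were lost (adjusted p = 0.708, 0.543 and 0.708, in that order). None of their single members passed over all genes. All 21 tested cellulose synthase genes had a positive log2 fold change, median 0.34, and the list was higher in RNAi by camera (adjusted p = 3.6e-08; adjusted p = 0.708 with an estimated correlation). None of the 21 rose. Gh_D05G2313 (CESA6) stood at 2.97 ± 1.05 FPKM in WT and 7.82 ± 5.26 in RNAi (limma adjusted p = 0.840). Gh_A05G3959 (CESA1) had 16.6 ± 2.48 and 21.5 ± 3.02 FPKM (0.840), and Gh_D05G0084 (CESA1) 22.3 ± 5.83 and 30.6 ± 6.26 (0.844). Arabinogalactan proteins, glycoproteins of the wall and plasma membrane, were positive in 48 of 60 members (camera adjusted p = 3.9e-05; adjusted p = 0.543 with an estimated correlation), and none rose. Gh_A05G1365 (AGP30) had 1.25 ± 0.345 and 3.64 ± 1.35 FPKM, Gh_A07G2174 (FLA7) 4.57 ± 2.05 and 12.5 ± 5.55, and Gh_D07G1687 (FLA7) 11.2 ± 2.82 and 28.5 ± 17.8. Expansins, which loosen the wall, were positive in 22 of 29 members (camera adjusted p = 0.00244; adjusted p = 0.708 with an estimated correlation), with 0 past the threshold over all genes and 1 adjusted over the list alone. Gh_A05G0808 (EXPA4) had 1.43 ± 0.325 FPKM in WT and 4.10 ± 1.07 in RNAi (limma adjusted p = 0.102). Gh_D05G0927 (EXPA4) had 2.77 ± 1.80 and 7.30 ± 1.78 (0.490), and Gh_A03G0885 (EXPA15) 1.69 ± 0.125 and 3.35 ± 0.931 (0.582). Xyloglucan-modifying enzymes were positive in 16 and negative in 14 of 30 members (camera adjusted p = 0.637), and pectin-modifying enzymes positive in 12 and negative in 8 of 20 (0.541). The xyloglucan genes of lowest p lay lower in RNAi without passing. Gh_D12G0806 (XTHB) had 30.7 ± 10.3 FPKM in WT and 11.8 ± 5.35 in RNAi (limma adjusted p = 0.489), Gh_D13G0290 (XTH28) 8.30 ± 2.14 and 4.22 ± 2.38 (0.823), and Gh_D11G2065 (XTH6) 19.7 ± 6.28 and 12.6 ± 2.77 (0.839), with RNAi replicate 3 at 17.4. With RNAi replicates 2 and 3 only, the xyloglucan list passed camera as higher in RNAi (adjusted p = 0.0290). Its camera adjusted p with an estimated correlation was 0.920 in the fit of all libraries.

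Tubulins were positive in 32 of 38 members (camera adjusted p = 5.5e-05; adjusted p = 0.708 with an estimated correlation). Of them 1 rose, TUBB2 above, and 37 did not pass. Among these were Gh_A06G0038 (TUBB1) at 2.15 ± 0.918 FPKM in WT and 4.63 ± 1.84 in RNAi and Gh_A01G0900 (TUBB1) at 1.56 ± 0.450 and 4.32 ± 2.70. The list named lipid transfer proteins was positive in 8 of 10 members (camera adjusted p = 0.00257; adjusted p = 0.708 with an estimated correlation), with 0 past the threshold over all genes and 2 adjusted over the list alone. Gh_A05G0073 (AZI1) had 1.60 ± 0.569 and 6.82 ± 2.84 FPKM (limma adjusted p = 0.149). Gh_D01G1505 (LTPG1) had 9.21 ± 2.96 and 12 ± 1.19 (0.845), and Gh_A08G1938 (LTL1, the symbol of a lipase) 1.78 ± 0.973 and 3.58 ± 0.824 (0.685). The list holds 2 LTL1 genes and leaves out YLS3, the symbol of a protein like lipid transfer proteins. In alternatives chosen after seeing the data, it passed without LTL1 (6 of 8 positive, camera adjusted p = 0.0216; adjusted p = 0.873 with an estimated correlation). It did not pass without LTL1 and with the 15 tested YLS3 genes (8 of 23 positive, camera adjusted p = 0.541), so its direction does not describe the family. Defence proteins were positive in 17 of 20 members (camera adjusted p = 2.7e-06; adjusted p = 0.543 with an estimated correlation). Gh_A04G0895 (STH-2, named after a pathogen-induced potato protein) rose from 1.04 ± 0.140 to 4.15 ± 1.06 FPKM (limma adjusted p = 0.0286). That call was lost without any 1 library other than RNAi replicate 3 or RNAi replicate 4 (adjusted p of up to 0.186). Its namesakes did not pass over all genes, and 2 members of the list rose when adjusted over the list alone. Gh_D04G1399 (STH-2) had 1.35 ± 0.0991 and 4.26 ± 1.2 FPKM (limma adjusted p = 0.0675; 0.0467 without RNAi replicate 4). Gh_A10G1512 (STH-2) had 0.281 ± 0.248 and 1.72 ± 1.49 FPKM, with RNAi replicate 2 alone at 4.28.

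Heat shock genes were the 1 list lower in RNAi, with 121 of 170 members negative (camera adjusted p = 5.4e-04; adjusted p = 0.873 with an estimated correlation), and none fell. Gh_D12G1364 (HSP17.5-M, a small heat shock protein) had 743 ± 97.5 FPKM in WT and 335 ± 189 in RNAi (limma adjusted p = 0.578). Gh_D11G0302 (HSF8, a heat shock transcription factor) had 1.66 ± 0.423 and 0.689 ± 0.0586 FPKM (0.370), and Gh_D03G1549 (HSP70, a chaperone) 3.48 ± 1.35 and 1.28 ± 0.808 (0.712). The position of the list differed among the libraries of both groups. Its mean log2(FPKM + 1) ranged from 3.79 in WT replicate 2 to 4.38 in WT replicate 3. In RNAi it ranged from 3.31 in replicate 6 to 4.22 in replicate 3, above the WT mean of 4.11. The list did not pass with RNAi replicates 2 and 3 only (camera adjusted p = 0.663). It passed with RNAi replicates 4 to 6 only (camera adjusted p = 4.6e-09), a difference that was not itself tested. The heat shock list lost its call without WT replicate 1 (camera adjusted p = 0.0888), WT replicate 3 (0.0700) or RNAi replicate 6 (0.0624). Without WT replicate 3, the expansin (0.507), arabinogalactan (0.186) and lipid transfer (0.272) lists lost theirs too. With a filter at 5 FPKM the expansin (0.275), lipid transfer (0.0834) and defence (0.140) lists did not pass. With array weights the expansin (0.0935), lipid transfer (0.429) and heat shock (0.749) lists did not, and with RNAi replicates 2 and 3 only neither did the lipid transfer list (0.0998). By the exact permutation test of list means over libraries, the lowest raw p was 0.0714, for tubulins and defence proteins. No list passed after adjustment, but with a smallest p of 0.0179 over 35 lists that outcome was nearly fixed in advance and says little.

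**Figure D2:**
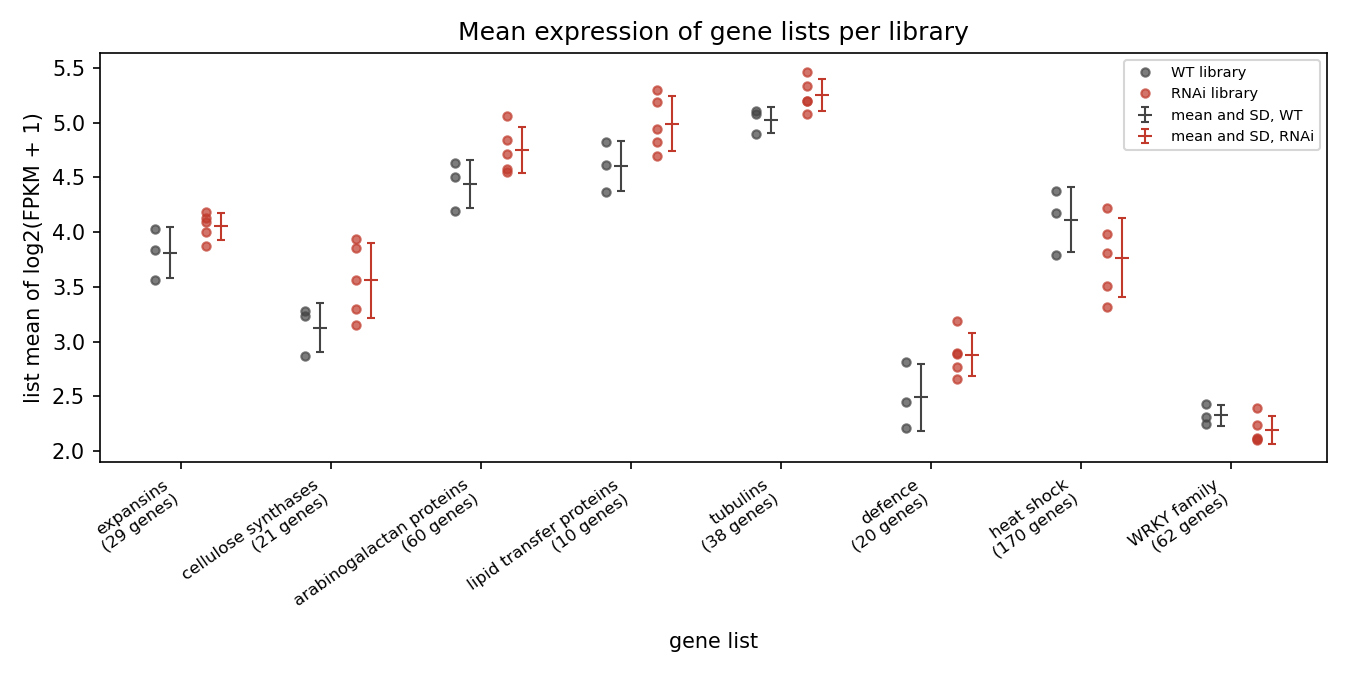
Mean log2(FPKM + 1) over the tested members of the 7 gene lists that passed camera and of the WRKY family, with a point per library and the mean ± SD of the 3 WT and 5 RNAi libraries. The libraries of both groups overlap in each list, and cellulose synthases averaged 3.13 ± 0.225 in WT and 3.56 ± 0.340 in RNAi.

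The other 28 lists did not pass camera at the preset correlation. Aquaporins, the water channels of membranes, came closest after the WRKY family (adjusted p = 0.0597; adjusted p = 0.708 with an estimated correlation), with 17 of 54 members at an unadjusted p under 0.05. Over all genes none passed the threshold, and 2 higher and 1 lower members did adjusted over the list alone. Gh_A03G0325 (TIP1-3, of the vacuole membrane) had 56.2 ± 13.2 FPKM in WT and 22.4 ± 8.67 in RNAi (limma adjusted p = 0.212). Gh_A03G0138 (PIP1-2, of the plasma membrane) had 9.34 ± 3.87 and 23.4 ± 7.67 (0.393) and Gh_A08G0940 (NIP5-1) 0.424 ± 0.149 and 1.72 ± 0.653 (0.381). Fry's mixed test, which asks whether members change in either direction, passed for aquaporins (adjusted p = 0.0213), tubulins (0.00198), defence proteins (0.00118) and photosynthesis genes (0.0142). Over 20 alternatives the aquaporin list passed camera in 8. It passed without WT replicate 1 (0.00622), WT replicate 2 (0.0143), RNAi replicate 2 (0.0385), RNAi replicate 4 (0.0458) or RNAi replicate 5 (0.0396), and did not without WT replicate 3 (0.860), RNAi replicate 3 (0.159) or RNAi replicate 6 (0.182) or with a filter at 5 FPKM (0.761). None of 92 MYB transcription factors, a family that includes regulators of fibre initiation, passed the threshold. Gh_D12G1628 (MYB39) had 2.91 ± 0.412 FPKM in WT and 1.13 ± 0.643 in RNAi (limma adjusted p = 0.491). Gh_D11G2407 (MYB5) had 2.29 ± 0.168 and 1.29 ± 0.268 (0.580), and Gh_A05G1126 (MYB26) 2.13 ± 1.27 and 5.92 ± 2.55 (0.582). Among markers of other tissues, none of 42 photosynthesis genes passed over all genes (8 at an unadjusted p under 0.05), and 2 higher and 1 lower did adjusted over the list alone. Gh_D07G1759 (RBCS, the small subunit of Rubisco) had 0.850 ± 0.376 FPKM in WT and 3.09 ± 0.846 in RNAi (limma adjusted p = 0.102), and Gh_A07G2172 (RBCS) 0.626 ± 0.226 and 3.61 ± 1.58 (0.129). Gh_D04G0269 (PSAN, of photosystem I) had 33.8 ± 5.73 and 23.0 ± 0.661 FPKM (0.310). The list passed camera as higher in RNAi with no filter (6.9e-05) and as lower with a filter at 5 FPKM (0.0146). With the filter used here its camera adjusted p was 0.813, and 0.943 with an estimated correlation. The median log2 fold change of the 42 genes was -0.06 and their mean 0.03. None of 8 seed genes passed, with 1 at an unadjusted p under 0.05.

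Upland cotton is an allotetraploid with an A and a D subgenome. Of the changed genes, 30 lay on A chromosomes among 16467 tested and 27 on D chromosomes among 17085 (Fisher's exact test, two-sided, p = 0.599). By the same exact test, genes that rose were on A in 9 cases and on D in 18 (p = 0.124). Genes that fell were on A in 21 cases and on D in 9 (Fisher's exact p = 0.0272, and 0.0816 adjusted over the 3 tests). Genes are not independent replicates, so these shares describe the lists only. Within chromosomes, 28 of the 57 changed genes had another changed gene within 100 gene numbers, in 11 groups. Among them were MRS2-3 with TFT6 on A01, YLS3 with DIR19 on A08 and ycf4 with CPX1 on A11. In 7 of the groups all changed genes rose or all fell. The other groups held both directions, as with MRS2-3 and TFT6 and with ycf4 and CPX1.

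**Figure D3:**
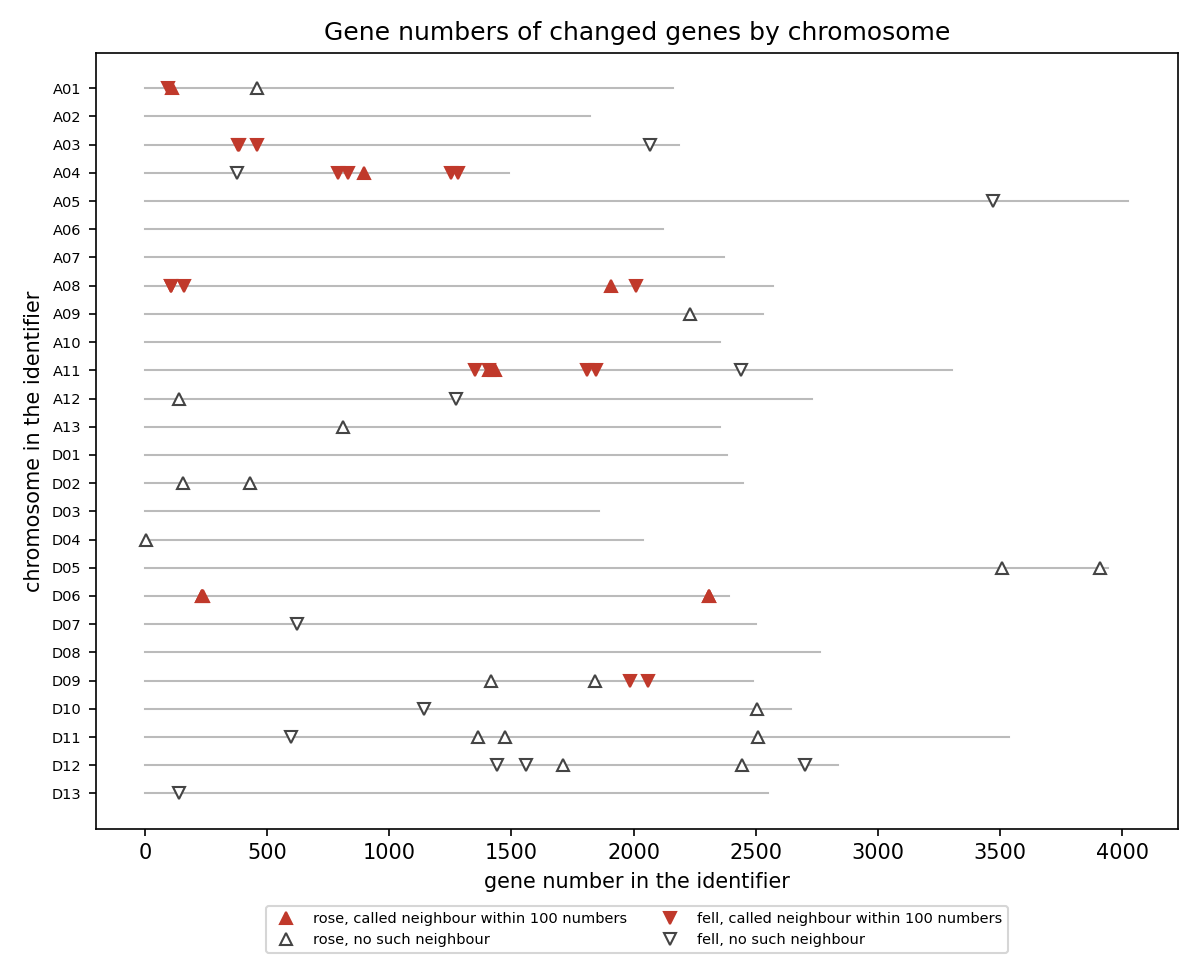
Gene numbers (x axis, from the identifiers) of the 57 changed genes on each chromosome (y axis), with upward triangles for genes that rose and downward triangles for genes that fell; grey lines span the tested genes. The 28 filled symbols are changed genes with another changed gene within 100 numbers.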

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

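The tests of the patterns weighed here on depth and on genes without a symbol were set before their results were seen, and the count over other splits of the libraries after it. Among 72 values tested for a library far from the other RNAi libraries, 5 stood out, against 3.60 that chance would give at 1 in 20. The gap to the nearest library, relative to the range, was too large for MRS2-3 in RNAi replicate 4 (3.22 FPKM, others 0.954 to 1.59), for LCAT3 in RNAi replicate 2 (1.11 FPKM, others 1.90 to 2.15), for Gh_D11G2065 (XTH6) in RNAi replicate 3 (17.4 FPKM, others 10.6 to 12.2), and for Gh_A10G1512 (STH-2) in RNAi replicate 2 (4.28 FPKM, others 0.521 to 1.60). In all 4 genes the direction of the difference from WT is the same without that library.

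The last of the 5 is the share of FPKM in genes without a symbol, 32.9% in RNAi replicate 4 against 27.4% to 28.3% in the other RNAi libraries. This library also had the lowest mean correlation with the others, 0.940 over all tested genes against 0.955 for the next. Among 2007 genes with a mean of at least 100 FPKM, where single reads matter little, its mean correlation was 0.772. The next lowest was 0.884, with an SD of 0.0141 between the others. Shallow depth therefore does not account for its distance among these genes. Whether depth adds to the gap over all tested genes, most of them lower, was not tested. Among the 27079 tested genes with a symbol its mean correlation was 0.957 against 0.961, within the SD of 0.00570. Genes without a symbol may therefore account for most of the gap over all tested genes. Which transcripts or material these genes stand for was not tested, and no biological explanation was tested.

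The number of genes changed in RNAi versus WT was compared with all other ways to split the 8 libraries into 3 and 5. The real split gave 57 genes and the highest other split 15, so 1 of 56 splits reached the real count. For genes changed at least 2-fold the real split gave 53 and the highest other 15, again 1 of 56. This argues against a random division of these libraries, at a share under 0.05. The 53 genes are among the 57, so the 2 counts are not separate tests. The splits cannot tell the silencing from any other difference between the WT and RNAi samples. The highest other split set WT replicates 2 and 3 with RNAi replicate 4 against the rest.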

How the results depend on the processing

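The counts of 57 genes and of 53 genes at 2-fold stayed within 1.5 times under both other scalings (52 and 53; 50 and 51), a pseudocount of 0.1, no filter, no trend and, added after seeing the data, robust empirical Bayes. They moved to 35 and 33 with a pseudocount of 0.01, to 36 and 31 with a filter at 5 FPKM (fewer genes tested), to 26 and 26 with RNAi replicates 2 and 3 only, to 28 and 28 with RNAi replicates 4 to 6 only (fewer libraries), and to 88 with array weights. Without each library in turn they ranged from 33 to 58 and from 32 to 57. Of the 57 genes, between 30 and 47 were called again in these fits, 26 in each of them, and 7 under every setting run. The lists past camera numbered 7, from 4 to 9 without each library, 0 with an estimated correlation, 0 by directional fry and 4 by mixed fry. The cause was not tested. Exact permutation of list means gave 0, an outcome nearly fixed by its smallest p of 0.0179 over 35 lists. Changes of direction with a call on one side were photosynthesis genes with the 5 FPKM filter (camera adjusted p = 0.0146), ribosomal proteins with RNAi replicates 4 to 6 only (0.0203) heat shock genes in 4 libraries without a block (0.654) and the lipid transfer list without LTL1 and with YLS3 (0.541), members chosen after seeing the data; without LTL1 alone it passed (0.0216). For the first 3 the cause was not tested. In the subgenome comparison, the test of all changed genes stayed above 0.05 in the 21 alternatives (0.0564 to 1), as did that of genes that rose. The test of genes that fell, unadjusted, was under 0.05 in 17 of 21 (1.8e-04 to 0.575). For lists and subgenomes, single libraries left out, RNAi replicates 4 to 6, array weights and no trend were added after seeing the data. The tests of genes that rose and fell were in the design, and running them under the alternatives was added after seeing the data. Only the numbers 2 and 3 are shared by both groups. In a replicate block over these 4 libraries, 311 genes passed, all 311 at 2-fold, and 12 lists, against 27, 27 and 10 in the same libraries without it. With the block, these libraries leave hardly any residual spread per gene. The calls then rest largely on the variance that limma shares across genes, so the higher count does not show a gain from pairing. Same-numbered libraries deviated with r of 0.35 and -0.09, and crossed ones with -0.01 and -0.31. With 2 pairs and no word in the labels, this does not settle whether the numbers pair the libraries, and they were treated as sharing only a number. WRKY16 was not identified, so no alternative was run for it. Read counts are unknown, so the limit that depth sets on low genes in RNAi replicate 4 could not be given.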

Other observations

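The tests of chance placement, of neighbouring copies and of the spread between libraries were chosen after the results were seen, and those of chromosome segments and of the shared shift before. Several genes past the threshold were too low for the naming rule and are given here after their values were seen. Gh_A01G0459 and Gh_A12G0139, both DRP5A (a dynamin-related protein of cell division), rose from 0.0753 to 3.03 and from 0.137 to 3.30 FPKM, and Gh_D06G2309 (NACK2, a kinesin of cell plate formation) from 0.312 to 2.32. The list of dividing-cell genes did not move with them: none of its 66 members passed limma's threshold, 2 had an unadjusted p under 0.05, and its camera adjusted p was 0.666. Gh_D02G0154 (ALS, named after acetolactate synthase) was listed at 0 in WT and averaged 3.10 FPKM in RNAi. Gh_A03G0379 (TOPP2, a protein phosphatase like TOPP4) fell from 2.78 to 0.0684 FPKM, whereas TOPP4 rose. Gh_D12G2702 (SAUR32, of the auxin-response list) fell from 4.71 to 0.263 FPKM, the 1 of 184 auxin genes to pass. Its namesake Gh_A13G2026 (SAUR32) went the other way without passing, from 0.0699 FPKM in WT to 1.95 in RNAi (limma adjusted p = 0.213).

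The changed genes lay near each other along the chromosomes. Of the 57, 23 had another changed gene 6 to 100 numbers away, against a median of 8 in 10000 random sets matched on expression (one-sided permutation p = 7.0e-04), which argues against chance placement. These 23 of the 28 have a neighbour beyond 5 numbers, which for them argues against tandem copies sharing reads. The rest, all on D06, have only nearer neighbours, so shared reads stay open there. Among them Gh_D06G0233 and Gh_D06G0237 are both named KLHL30. A candidate explanation is chromosome segments that differ between the RNAi and WT plants, such as segments of another parent. Of 1464 uncalled tested genes in windows around the 11 groups, 7.04% had an unadjusted p under 0.05, against a median of 5.66% in random windows (one-sided permutation p = 0.0368). This is a hypothesis noticed and tested on the same data, and the excess is small. A response of neighbouring genes to the silencing stays open and untested, and 29 of the 57 genes had no such neighbour. Gene numbers were taken to follow position because 6.05% of genes shared a symbol with the next number and 0.0266% with a gene 500 numbers away.

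The lists of cellulose synthases and arabinogalactan proteins stood higher in RNAi by camera at the preset correlation and lost the call with an estimated correlation (adjusted p = 0.708 and 0.543). The mean of the cellulose synthase list did not separate the groups (exact permutation p = 0.143), so spread between libraries may account for the difference. After subtraction of group means the list means of both lists went together over the 8 libraries (Pearson r = 0.881, permutation p = 0.00595). Spearman rho was 0.833 (permutation p = 0.0154). Without RNAi replicates 2 and 6, the 2 farthest in the cellulose synthase list, r was 0.982 (permutation p = 0.00278), with the group means kept. Centred values were permuted freely across both groups, although centring ties those of each group together, so these p values are approximate. A shift shared by these 2 lists within groups could give this correlation, for instance in fibre stage, which was not measured. Other lists were not correlated in this way, so a shift of whole libraries was not shown. The expansin list ranked otherwise among the RNAi libraries, with its highest mean in replicate 4 (4.18) and its lowest in replicate 5 (3.87). The cellulose synthase list had means of 3.29 and 3.85 in these. An effect of the silencing on top of such a shift cannot be excluded and stays open.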
